A study of Homo sapiens with 17 samples.

How the data were processed

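Messenger RNA was measured in 17 libraries of memory CD4 T cells sorted from thawed blood mononuclear cells of 10 donors. Per the labels' protocols, cells positive for CD4 and CD45RO were split by the surface level of the chemokine receptor CXCR5 into a high (CXCR5hi) and a low (CXCR5lo) fraction and sorted directly into lysis reagent. Library titles mark both fractions as CXCR5 positive (POS), so by its label CXCR5lo is not a CXCR5-negative fraction. The stated gate names no marker to exclude monocytes or B cells. From 1 to 5 ng of total RNA, cDNA was amplified by Smart-seq2 over 16 cycles and made into Nextera XT libraries. No molecular identifiers are named, so amplified copies of 1 molecule could not be collapsed, and floors and intervals given here cover counting error only. Donors had allergy and no stated immunotherapy (called allergic) or were undergoing allergen-specific immunotherapy (AIT).

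The deposited table holds raw counts per gene symbol, not normalized, with 1 column per library. The submitters' processing notes name hg19, TopHat 1.4.1, SAMtools and HTSeq without a role or an order. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Genes with near-identical copies, such as HSPA1A and HSPA1B, and genes overlapping another on the opposite strand are therefore uncertain. The table has 21762 genes or transcripts, and 0 of its lines name no gene. Of these, 31 (Y-linked genes, genes of X inactivation and CD24) were removed before anything was computed, which left 21731. A current RefSeq symbol matched 18439, and a further 2076 matched an older symbol only. In 27 cases the symbol had been turned into a date. They were tested and are not named. All 17 counts were 0 for 2402 genes. Mitochondrially encoded genes number 0 in the table, so their share could not be computed. The reference annotation at hand is of another build than hg19, so no coordinates are given. It served for names, for the removal of Y-linked genes and for transcript lengths.

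Total counts ran from 7229276 to 14023607 per library, and 13635 to 15499 genes had a count. Groups followed the labels: CXCR5hi allergic (n = 5), CXCR5lo allergic (n = 5), CXCR5hi AIT (n = 3) and CXCR5lo AIT (n = 4). Replicate numbers follow deposition order and pair nothing. The donor of each library came from the labels: 7 donors gave both subsets, 5 of them allergic and 2 under AIT. The deviations of the 2 libraries of a donor from their group means correlated with r from 0.244 to 0.664 (median 0.439, across genes). Libraries of different donors of the same therapy group gave r from -0.492 to 0.395, and in 7 of 7 pairs the CXCR5hi library correlated best with the CXCR5lo library of its own donor. Duplicated libraries were checked for, and the lowest chi-square per degree of freedom between libraries of a group was 44.0.

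Differences were tested with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood test with TMM scaling. Genes were filtered by filterByExpr at a minimum count of 10 over the 4 groups, which kept 12946 genes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p given without another tool's name is from this test. The 3 comparisons between subsets and their difference between therapy groups used donor as a block, so unpaired libraries added to scaling only. The comparisons of AIT with allergic donors used the 4 group means without a block. Each model estimated its own spread. Fold changes are log2 values with standard errors (SE), and levels of single genes are normalized counts (CPM, from TMM-scaled library sizes) as mean and SD over libraries. CPM summed over several genes used library totals without TMM scaling. Where every library of a group had 0 counts, the fold was computed against a floor of 3 counts over the group.

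Of 17 gene lists, 16 had enough tested genes for camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry were alternatives. Summed CPM of marker lists and library measures were compared by two-sided exact permutation of group labels or by exact sign flips within donors, 48 relations in all, with 0.1 CPM added before the log. Named genes follow a rule. It takes 14 genes of follicular, regulatory and other T cells wherever tested, up to 8 higher and 8 lower genes with the smallest p among those that passed (with the same sign in every pair for subset comparisons), and up to 4 genes of each list. Immunoglobulin, T cell receptor and HLA genes are not named by the second part unless at most 5 genes passed. A gene outside the rule is said to be chosen after its values were seen. The designs, lists, naming rule and most alternatives were fixed before the data were examined. Those concerning donor codes, immediate early counts, transcript length and the removal of marker genes were added later.

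The steps were tested on simulated data with counts drawn from the real means and library sizes and 100 genes changed at each of 2 fold sizes. At 4-fold, 80 were recovered in CXCR5hi against CXCR5lo over all donors (12629 genes), 72 in allergic donors (12665 genes) and 54 in AIT donors (12678 genes). For AIT against allergic donors, 36 were recovered in CXCR5hi and 46 in CXCR5lo (12575 genes each), and 49 for the difference between therapy groups (12649 genes). At 2-fold, the numbers recovered were 52, 48, 17, 2, 4 and 5 in that order. False calls were 8 of 140, 7 of 127, 9 of 80, 1 of 39, 0 of 50 and 1 of 55. The shares over all donors (8 of 140), in allergic donors (7 of 127) and in AIT donors (9 of 80) lay above the threshold of 0.05, the last by the most. For AIT against allergic donors, neither donor nor code series effects were simulated, so those false calls do not measure error in the real comparisons.

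Alternatives were RLE scaling, no count filter or a stricter 1 (50 counts in 3 libraries), DESeq2 1.42.0, limma-voom with donor as a random effect, omission of immunoglobulin, T cell receptor and HLA genes, fits without the block, subsets of libraries, and each library left out in turn. Libraries carry 1 of 2 tags in their titles, and donor codes fall into 2 series, the first of which holds 3 allergic donors and 0 AIT donors. Neither is explained in the labels, and both were treated as possible batches. For length, the longest transcript of each symbol in the reference annotation was used, which 88.3% of tested genes had. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.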

Results

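Gene counts were compared between 2 fractions of circulating memory CD4 T cells, both labelled CXCR5 positive, and between 2 groups of donors. CXCR5 is the chemokine receptor that guides follicular helper T cells (Tfh) and follicular regulatory T cells (Tfr) into B cell follicles, and the series asks how allergen-specific immunotherapy shifts the balance of these cells in blood. There were 5 CXCR5hi and 5 CXCR5lo libraries from 5 allergic donors, and 3 CXCR5hi and 4 CXCR5lo libraries from 5 AIT donors. Depth was 7229276 to 14023607 counts per library. Other libraries of the study were not analysed here.

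The first comparison asked how the CXCR5hi fraction differs from the CXCR5lo fraction of the same donor. The sorted receptor's own transcript was higher in CXCR5hi in 7 of 7 donors (log2 fold change 1.10, SE 0.14, adjusted p = 0.00269), at 240.5 ± 122.8 CPM against 118.6 ± 67.96 CPM (SD, n = 5 each) in allergic donors. Cytotoxic and regulatory T cell genes were lower. The granule protease gene GZMA fell by 2.64 on the log2 scale (SE 0.26, adjusted p = 0.000882), and FOXP3, the master transcription factor of regulatory T cells, fell by 3.24 (SE 0.43, adjusted p = 0.00285), each in 7 of 7 donors. FOXP3 stood at 1.502 ± 1.52 CPM in CXCR5hi and 15.1 ± 7.20 CPM in CXCR5lo libraries of allergic donors (SD, n = 5 each). CTLA4, an inhibitory receptor, fell by 1.18 and GATA3, the lineage factor of Th2 cells, fell by 1.22.

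**Figure D1:**
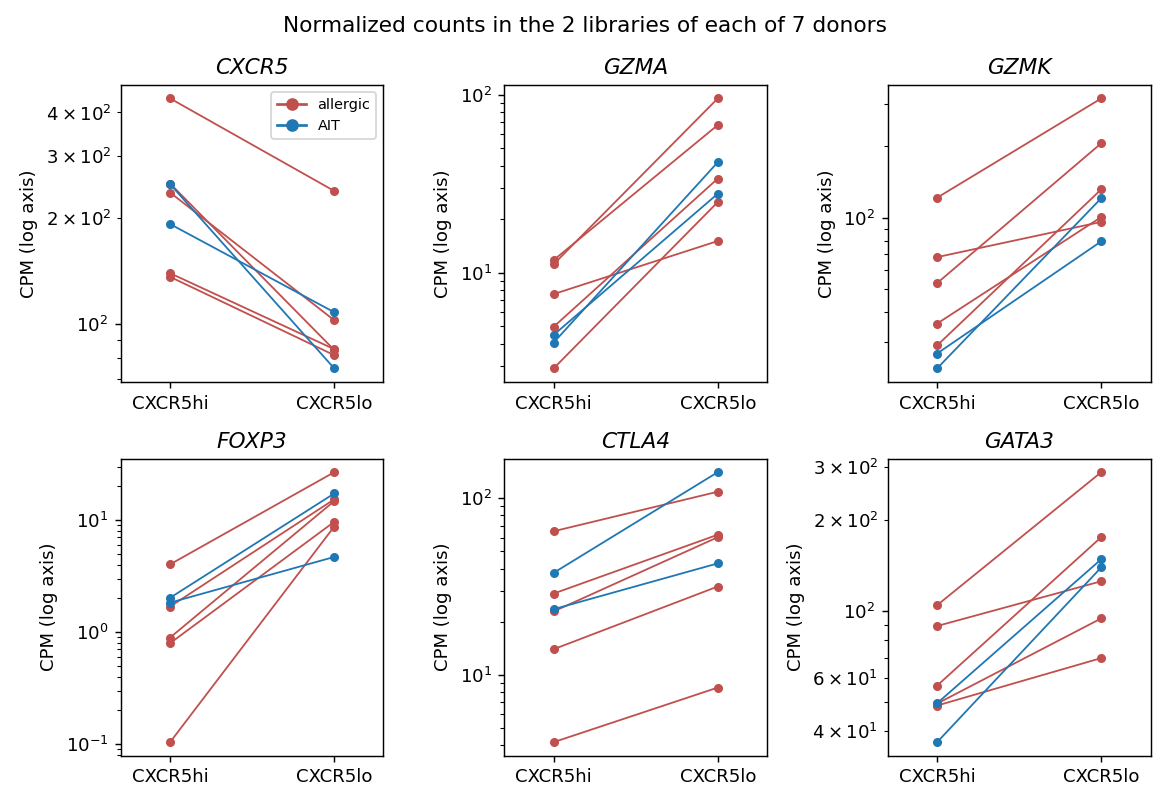
Normalized counts (CPM, log axis) of CXCR5, GZMA, GZMK, FOXP3, CTLA4 and GATA3 in the CXCR5hi and CXCR5lo libraries of 7 donors. Each line joins the 2 libraries of 1 donor, 5 allergic (red) and 2 AIT (blue). CXCR5 was higher in the CXCR5hi library in 7 of 7 donors, and the remaining genes were lower.

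Over all donors, 79 of 12946 genes passed, 8 higher and 71 lower in CXCR5hi, and 77 of the 79 had the same sign in 7 of 7 pairs. Beside CXCR5, the higher genes were AK5 (1.09 ± 0.15, log2 fold change ± SE), TMIGD2 (1.09 ± 0.18), a costimulatory receptor of naive and memory T cells, NUCB2 (0.73 ± 0.12), IGFBP3 (1.31 ± 0.22), PITPNC1 (0.57 ± 0.11), the kinase gene PASK (0.51 ± 0.11) and RASGEF1B (0.87 ± 0.18). With 1 library left out, CXCR5 and AK5 passed in 17 of 17 fits, TMIGD2 and NUCB2 in 15 and IGFBP3 in 13. PITPNC1 and PASK passed in 6 of 17 and RASGEF1B in 5. These fits overstate stability. Without an unpaired library (CXCR5hi AIT replicate 3, CXCR5lo AIT replicate 3 or 4) little but scaling and filtering changes. Those fits kept 79, 78 and 77 of the 79 calls. Each other fit removes the pair of 1 donor, and each pair is removed 2 times. Among the lower genes were the phosphatase gene DUSP4 (-2.04 ± 0.22), the decoy receptor gene LAIR2 (-1.67 ± 0.19), CHN1 (-2.98 ± 0.38), PRDM1 (-1.05 ± 0.14), which encodes the Blimp-1 repressor that opposes BCL6, and RGS1 (-1.62 ± 0.21). Without the donor block 9 genes passed, 100% of them lower. 26 passed without the 2 allergic donors whose libraries had the highest immediate early counts, 96.15% of them lower. DESeq2 called 198, 75.76% of them lower, so the number of higher genes depends on the fit.

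Of 20 tested regulatory T cell genes, 9 fell (13 adjusted over the list alone) and 0 rose, with a median log2 fold change of -1.12. DUSP4, CTLA4, FOXP3 and PRDM1 were the 4 with the smallest p. IL2RA, the high-affinity IL-2 receptor chain, did not pass (-0.33 ± 0.29, adjusted p = 0.897), nor did the cytokine gene IL10 (0.38 ± 1.19). Of 19 cytotoxic genes, 6 fell (11 adjusted over the list alone), among them GZMA, GZMK (-1.64 ± 0.19), CCL5 (-1.90 ± 0.24) and CST7 (-1.44 ± 0.24). Of 13 Th1 genes, 4 fell (6 adjusted over the list alone): IFNG (-1.61 ± 0.25), CXCR3 (-1.13 ± 0.18), IL18R1 (-1.36 ± 0.27) and IL12RB2 (-2.92 ± 0.58). Of 7 Th2 genes, GATA3 and the leukotriene receptor gene CYSLTR1 (-1.65 ± 0.26) fell (3 adjusted over the list alone). CXCR6 (-3.97 ± 0.72) was the 1 of 15 Th17 genes that fell (2 adjusted over the list alone), and CXCR6 and CXCR3 were the 2 of 21 homing receptors (8 adjusted over the list alone, with 1 higher). MKI67 (-2.93 ± 0.61) was the 1 of 22 proliferation genes (5 adjusted over the list alone). These 7 lists were lower as sets by camera with the preset and with an estimated correlation. With the latter, adjusted p was 0.000266 for regulatory T cell, 0.00168 for Th1, 0.00582 for cytotoxic and Th2, 0.0109 for Th17 and homing, and 0.0118 for proliferation genes. Not all single calls were stable when 1 library was left out. DUSP4, CTLA4, FOXP3, PRDM1, GZMA, GZMK, CCL5, IFNG, GATA3 and CYSLTR1 passed in 17 of 17 such fits. CXCR3 passed in 15, CST7 in 14, IL18R1, IL12RB2 and CXCR6 in 6 each, and MKI67 in 3. The fits without an unpaired library, which hardly test these calls, are among the 17.

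Follicular helper genes were lower as a set at the preset correlation only. Of 18 tested, CXCR5 rose and the surface glycoprotein gene CD200 fell (-1.55 ± 0.23), with 1 higher and 3 lower adjusted over the list alone. PDCD1, the PD-1 checkpoint receptor, was lower in 7 of 7 donors without passing (-0.65 ± 0.17, adjusted p = 0.167), and neither ICOS (-0.24 ± 0.10) nor BCL6, the Tfh lineage factor (-0.32 ± 0.31), passed. IL21 and IL4 had too few counts to be tested, at most 26 and 6 per library. For the list, adjusted p was 0.00716 at the preset and 0.179 with an estimated correlation. The same held for immediate early genes (0 of 23 passed, 2 adjusted over the list alone), with adjusted p = 0.00155 at the preset and 0.203 with an estimated correlation. Of 21 interferon response genes 0 passed (1 higher and 3 lower adjusted over the list alone), with adjusted p = 0.0459 at the preset and 0.107 with an estimated correlation, and the set was lower by fry (adjusted p = 0.0262). By fry, adjusted p was 0.0708 for Tfh and 0.154 for immediate early genes. Naive and central memory genes did not pass as a set (median 0.01, mean -0.02, adjusted p = 0.319). CCR7, which guides T cells into lymph nodes, was higher in 7 of 7 donors without passing (0.31 ± 0.10, adjusted p = 0.334), and the Th17 receptor CCR6 stood at -0.28 ± 0.12.

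Markers of other cell types were compared between subsets as well. Camera passed none of the B cell (adjusted p = 0.968), monocyte and myeloid (0.117), CD8 and NK cell (0.871), platelet (0.12) and heat shock (0.5684) lists. By fry, which does not compare a set with other genes, platelet markers were lower over all donors, in allergic donors and in AIT donors (adjusted p = 0.0159, 0.0236 and 0.0214). The erythroid list had 1 tested gene, HBB (-0.15 ± 0.66). Summed platelet marker CPM was 1.71-fold lower in CXCR5hi (exact sign-flip p = 0.0156, the smallest 7 pairs allow, adjusted p = 0.214 over 48 relations).

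**Figure D2:**
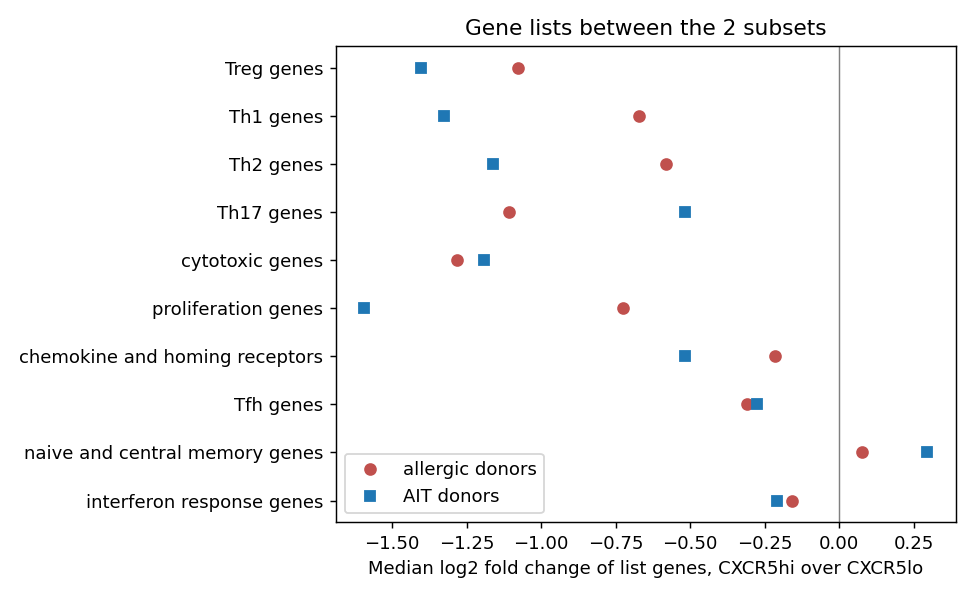
Median log2 fold change (x axis, CXCR5hi over CXCR5lo) of the tested genes of 10 gene lists (y axis) in allergic donors (red circles, 5 pairs) and AIT donors (blue squares, 2 pairs). The median of regulatory T cell genes was -1.08 in allergic and -1.40 in AIT donors.

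Within the 5 allergic donors, 3 genes rose (CXCR5, AK5 and TMIGD2) and 28 fell. GZMA fell by 2.50 (SE 0.30, adjusted p = 0.0132), FOXP3 fell by 3.65 (SE 0.47) and CHN1 fell by 2.42 (SE 0.31). DUSP4, LAIR2, GZMK, PRDM1, CCL5, CTLA4, GATA3, CD200 and CYSLTR1 fell as well, with log2 fold changes between -2.02 and -1.01. Of the regulatory T cell list 4 of 20 fell (10 adjusted over the list alone), of the cytotoxic list 3 of 19 (12 adjusted over the list alone) and of the Th1 list 0 of 13 (6 adjusted over the list alone). CXCR3 did not pass (-1.05 ± 0.22, adjusted p = 0.117). As sets, the same 7 lists were lower as over all donors, with adjusted p between 0.00133 and 0.033 with an estimated correlation. Tfh and immediate early genes were lower and monocyte and myeloid markers higher at the preset correlation, with adjusted p = 0.204, 0.204 and 0.52 with an estimated correlation. The count is fragile: 0 genes passed in edgeR without the block (255 at unadjusted p under 0.05, and 95 by DESeq2 with the block), and 2 and 104 in the donors of each title tag alone. 0 passed without CXCR5hi replicate 2 or CXCR5lo replicate 1, and 2 to 17 without any other allergic library.

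In the 2 AIT donors with both subsets, 2 genes rose and 19 fell, and with the trend of fold change with transcript length removed 1 rose and 17 fell. FTSJD1 (2.35 ± 0.40) and WDR36 (1.61 ± 0.27) were higher in CXCR5hi. CHN1 (-4.71 ± 0.57, adjusted p = 0.00721), the mitochondrial carrier gene UCP2 (-1.62 ± 0.20), the transcription factor gene BHLHE40 (-2.50 ± 0.32), the galectin gene LGALS3 (-3.55 ± 0.54), TALDO1 (-1.77 ± 0.27), IL32 (-1.41 ± 0.22), HMGB2 (-1.62 ± 0.26), GZMA (-3.00 ± 0.49), GZMK (-1.98 ± 0.35) and CLU (-3.60 ± 0.59) were lower. IL2RA (-1.81 ± 0.31) and GATA3 (-1.75 ± 0.29) fell too, each with adjusted p = 0.0351. HLA-DRA, chosen after its values were seen, fell by 4.02 (SE 0.36). CXCR5 was higher in 2 of 2 donors without passing (1.28 ± 0.26, adjusted p = 0.0989), and FOXP3 stood at -2.24 ± 0.71 (adjusted p = 0.26). Of 20 regulatory T cell genes 1 fell (11 adjusted over the list alone), and the set was lower (adjusted p = 0.00577 with an estimated correlation). Th1, Th2, homing and proliferation genes were also lower as sets (adjusted p = 0.0438 each with an estimated correlation). The cytotoxic set was lower at the preset correlation (2 of 19 fell, 7 adjusted over the list alone), with adjusted p = 0.102 with an estimated correlation. The calls rest on 2 pairs, and in 1 of them the 2 libraries carry different title tags, so subset and tag cannot be told apart there: 0 genes passed without CXCR5hi replicate 1 or CXCR5lo replicate 2, 6 and 5 without CXCR5hi replicate 2 and CXCR5lo replicate 1, and 1 without the donor block. Allergic and AIT donors shared 8 called genes, all in the same direction, where 0.0503 would be shared by independent lists. Both lists came from 1 fit with a shared spread estimate, so they were not independent and 0.0503 is no fair benchmark.

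Whether the difference between subsets itself depends on therapy was tested directly. HLA-DRA, an antigen-presenting MHC class II chain, was the 1 gene that passed (-3.15 ± 0.39, adjusted p = 0.0241). It stood at 38.6 ± 7.32 CPM in CXCR5hi and 70.9 ± 15.8 CPM in CXCR5lo libraries of allergic donors (SD, n = 5 each), and at 2.22 ± 1.34 CPM (SD, n = 3) and 44.2 ± 29.7 CPM (SD, n = 4) in those of AIT donors. None of the tested follicular or regulatory genes passed: the difference was 0.26 ± 0.30 for CXCR5, -0.02 ± 0.39 for PDCD1, 1.41 ± 0.83 for FOXP3 and -2.02 ± 0.36 for IL2RA (adjusted p = 0.245). Of the 16 lists 0 passed by camera and 0 with an estimated correlation, and the smallest adjusted p was 0.0522 (proliferation genes). HLA-DRA was called in 8 of 17 fits with 1 library left out. Among these 8 are the fits without an unpaired library (CXCR5hi AIT replicate 3, CXCR5lo AIT replicate 3 or 4), which hardly test the call. In edgeR without the donor block 0 genes passed (184 at unadjusted p under 0.05, and 20 by DESeq2 with the block). 0 passed without CXCR5hi allergic replicate 1, 2, 4 or 5, CXCR5lo allergic replicate 2, 4 or 5, CXCR5hi AIT replicate 1 or CXCR5lo AIT replicate 2.

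The comparison of AIT with allergic donors asked what differs with therapy within each subset. In both subsets most of the genes that passed were genes of monocytes and platelets, which were lower in AIT donors. LYZ, the lysozyme gene abundant in monocytes, fell by 4.47 in CXCR5hi (SE 0.65, adjusted p = 0.00933), from 116 ± 70.5 CPM (SD, n = 5) to 5.20 ± 1.08 CPM (SD, n = 3). In CXCR5lo it fell by 4.22 (SE 0.56, adjusted p = 0.00392), from 119 ± 98.8 CPM (SD, n = 5) to 6.31 ± 2.56 CPM (SD, n = 4). The platelet chemokine gene PPBP had 0 counts in every AIT library and was at least 66.9-fold lower in CXCR5hi and at least 71.0-fold lower in CXCR5lo, with a floor of 3 counts over the group. None of the 12 tested genes among the 14 that the naming rule always takes passed in either subset.

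In CXCR5hi, 13 genes passed. MLL2 (1.88 ± 0.34), a histone methyltransferase gene, SMCHD1 (2.06 ± 0.39) and BACH2 (1.94 ± 0.37), a repressor that restrains effector differentiation, were higher in AIT, each with adjusted p = 0.0483. These calls are fragile. None of the 3 passed in edgeR with RLE size factors, without immunoglobulin, T cell receptor and HLA genes, with the length trend removed, with the 2 compared groups alone or with code series as a term, where adjusted p ran from 0.0507 to 0.258. All 3 passed by DESeq2. TNFRSF4, the costimulatory receptor OX40 and 1 of 20 regulatory T cell genes, fell by 2.05 (SE 0.33, adjusted p = 0.0202). SERPINA1, FCN1 (-7.08 ± 1.29), S100A8 (-5.22 ± 0.98), CST3 (-3.35 ± 0.63) and IFI30 (-4.88 ± 0.92) were lower. TYROBP had 3 counts over the 3 AIT libraries against 41 to 186 per allergic library, and SERPINA1 had 5 against 69 to 207. HLA-DRA was lower as well (-4.11 ± 0.52, adjusted p = 0.00299) and was chosen after its values were seen. FOXP3 (0.01 ± 0.81), CXCR5 (-0.04 ± 0.46), PDCD1 (-1.03 ± 0.69) and IL10 (-0.31 ± 1.34) did not pass. For 976 genes (7.54%) the groups did not overlap, where 2 of 56 splits would do so by chance if libraries were interchangeable. They were not, since 1 of the 2 donor code series holds allergic donors only. The excess is therefore no evidence of a therapy effect.

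In CXCR5lo, 8 genes passed and all were lower in AIT: LYZ, S100A8, SERPINA1, S100A9 (-6.71 ± 1.03), CPVL, VCAN, CYBB and PPBP. The group fit takes libraries of a donor as independent. With donor as a random effect (limma-voom), 1 of these 8 genes passed in CXCR5lo (LYZ), and 5 of the 13 in CXCR5hi. SERPINA1 had 0 counts in every AIT library and was at least 138-fold lower. S100A8, CPVL and VCAN had 1 count each over the 4 AIT libraries and CYBB 2. FOXP3 (-0.99 ± 0.69), CXCR5 (0.50 ± 0.42), PDCD1 (0.57 ± 0.60) and IL10 (1.61 ± 1.20) did not pass. For 277 genes (2.14%) the groups did not overlap, where 2 of 126 splits would do so by chance if libraries were interchangeable. Donor code series and therapy overlap here too, so the excess is no evidence of a therapy effect.

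**Figure D3:**
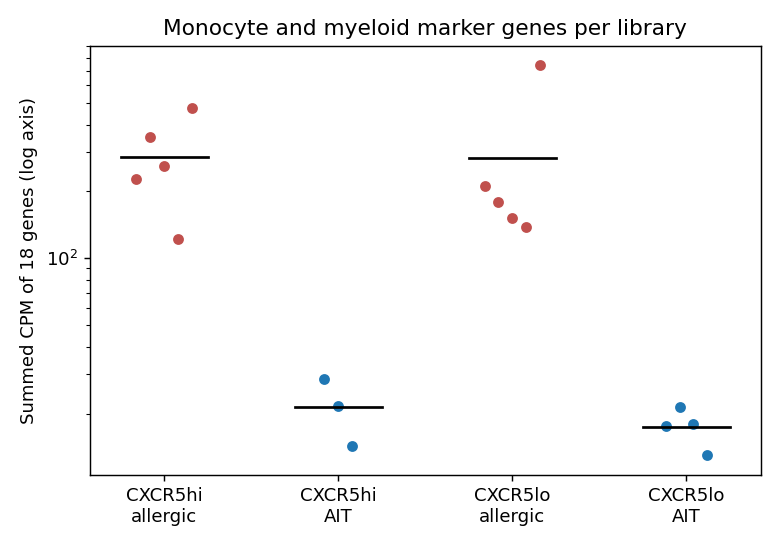
Summed CPM of 18 monocyte and myeloid marker genes (y axis, log axis) in each library of the 4 groups (x axis), with the group mean as a line. Allergic libraries (red) lie between 122 and 738 CPM, and AIT libraries (blue) between 13.0 and 28.6 CPM.

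Of 18 monocyte and myeloid markers, 6 fell in CXCR5hi and 5 in CXCR5lo (15 in each, adjusted over the list alone). Their median log2 fold change was -4.21 and -4.44, or -3.96 and -4.26 with genes at 0 set to their bound, and the set was lower with an estimated correlation (adjusted p = 0.0345 and 0.00854). Their summed CPM was 12.6-fold lower in CXCR5hi (exact permutation p = 0.0179, the smallest possible with 3 against 5) and 13.1-fold lower in CXCR5lo (exact permutation p = 0.00794, the smallest possible with 4 against 5), with adjusted p = 0.214 over 48 relations for both. Other marker sums were lower by less. Summed B cell CPM was 2.31-fold lower in CXCR5hi and 1.52-fold lower in CXCR5lo (exact permutation p = 0.0357 and 0.246). Summed CD8 and NK cell CPM was 2.05-fold and 2.26-fold lower (exact permutation p = 0.0357 and 0.0476), and summed platelet CPM 3.76-fold and 3.25-fold lower (exact permutation p = 0.0536 and 0.0238). None of these passed over the 48 relations (adjusted p of 0.229 or more). The permutations take libraries as interchangeable across donor code series. B cell sums were 70.45 to 94.04 CPM in the series of allergic donors only. In the other series, allergic libraries had 36.2 and 31.36 in CXCR5hi and 29.25 and 21.7 in CXCR5lo. AIT libraries had 21.48 to 28.14 and 26.64 to 50.72. There, CD8 and NK cell sums in CXCR5lo were 15.96 and 12.39 in allergic and 4.686 to 15.95 in AIT libraries. Both sums overlapped between groups in CXCR5lo, not in CXCR5hi. Platelet sums did not overlap within the series with both therapy groups, at 38.97 CPM or more in allergic and 22.75 or less in AIT libraries. Of 8 platelet markers 1 fell in each subset (5 adjusted over the list alone). That set was lower at the preset correlation and by fry (adjusted p = 0.0207 and 0.0182), with adjusted p = 0.171 and 0.0826 with an estimated correlation. Cytotoxic genes were lower as a set at the preset correlation in both subsets (0 of 19 passed, and 0 and 2 adjusted over the list alone), with adjusted p = 0.352 and 0.524 with an estimated correlation. Homing receptors were lower in CXCR5hi at the preset correlation and by fry (adjusted p = 0.00527; 0 of 21 passed, 0 adjusted over the list alone), with adjusted p = 0.117 with an estimated correlation. The remaining lists did not pass, with camera adjusted p of 0.193 or more in CXCR5hi and 0.0984 or more in CXCR5lo.

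Donor code series and therapy overlap, since 1 of the 2 series holds allergic donors only. Within the other series, 2 genes passed in CXCR5hi and 1 in CXCR5lo, and 3 and 5 passed with code series as a term. LYZ passed in all 12 of the alternatives in which it was tested in each subset, leave-outs aside. 0 genes passed in CXCR5hi without AIT replicate 2 or 3, 1 without AIT replicate 1, and 2 to 5 without allergic replicate 1, 2, 3 or 5. In CXCR5lo, 3 or 4 passed without any 1 of the 4 AIT libraries and 14 without allergic replicate 3.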

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

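The test of donor code series for monocyte genes, the tests of marker lists for HLA-DRA, the test of length on SMCHD1 and BACH2 alone, and the removal of the length trend were chosen after the results they address were seen. The remaining tests were planned, but that of a single library had asked for 3 libraries above every allergic one, and 2 were taken as enough after the slopes were seen.

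Summed monocyte and myeloid CPM was 12.6-fold lower in AIT libraries of CXCR5hi and 13.1-fold lower in those of CXCR5lo, and 1 of 8 platelet genes passed as lower in each subset (list adjusted p = 0.171 and 0.0826 with an estimated correlation). Within the code series that holds both therapy groups, the lowest allergic library was at least 4.27 times the highest AIT library in each subset, which argues against code series as the whole cause, although this rests on 2 allergic donors. Monocyte material in the allergic samples is a candidate source, since the sort took cells positive for CD4 and CD45RO and names no exclusion of such cells. Between the 2 libraries of an allergic donor, 77.65% of 17 other list genes moved with LYZ, against a median of 51.76% in 10000 random lists, of which 0 were as high; by donor the share was 47.06% in 1 of the 5, below that median, and 70.59% to 100% in the others. The random lists held unrelated genes, so any genes that vary together would exceed them, whatever the source. Only allergic donors entered this test, so it cannot tell why AIT libraries were lower. Cells and free RNA cannot be separated by it either, and a biological difference with therapy in monocytes was not tested.

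Long transcripts were higher and short transcripts lower in CXCR5hi AIT libraries: the median log2 fold change of AIT over allergic donors ran from -0.28 in the shortest to 0.29 in the longest of 5 equal bins of genes, and the same bins ran from -0.12 to 0.21 between the subsets of AIT donors and from -0.17 to 0.30 for the difference between therapy groups. Length slopes per library gave an exact permutation p = 0.0536 (two-sided, 3 against 5). Of the 3 CXCR5hi AIT libraries, 2 had a slope above every allergic library (0.1345 and 0.1424 against at most 0.0494), which argues against a single library as its carrier, and within the code series with both groups 73.33% of the gap remained, which leaves code series open. With the trend removed, at least 84.65% of the log2 fold change was kept (66.24% less 1 SE), which argues against length as the main source of the higher SMCHD1 and BACH2. This bar of 1 SE was laxer than the 2 SE used for HLA-DRA, and at 2 SE the verdict would not hold for BACH2. Both calls ended: SMCHD1 went from 2.06 ± 0.39 to 1.80 ± 0.35 (adjusted p = 0.0754) and BACH2 from 1.94 ± 0.37 to 1.64 ± 0.36 (adjusted p = 0.146). MLL2 had no matched length, so length stays open for it, and its call ended too (adjusted p = 0.0616) at an unchanged log2 fold change of 1.88.

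HLA-DRA was lower in CXCR5hi than in CXCR5lo by more in AIT than in allergic donors, a difference of -3.152 on the log2 scale that passed the test of the difference itself, but chance was not excluded, since 2 of 21 splits of the donors gave as many genes, and 0 genes passed by limma-voom or in edgeR with no replicate block. Fewer myeloid cells in CXCR5hi AIT libraries are argued against as the whole cause of the fall in AIT donors, but only weakly. Counts were low: 4 of the 18 list genes had 10 counts in every paired CXCR5lo AIT library. Summed myeloid CPM was higher in CXCR5hi in 2 of 2 pairs (28.6 against 21.4, and 21.7 against 17.5), although 11 of the 18 genes were lower and 7 higher. LYZ was about level in the first pair (3.954 against 3.752 CPM) and lower in CXCR5hi in the second (5.753 against 7.625 CPM). The highest ratio of HLA-DRA (TMM-scaled) to that sum (unscaled) in an allergic library was 0.497. At this ratio, the CXCR5lo sum allows at most 13.09% and 63.61% of the fall in HLA-DRA in the 2 pairs. Whether myeloid material in the allergic libraries, with 122 to 738 CPM in that sum, shrank their log2 difference was not tested. It therefore stays open for the difference between therapy groups. Removal of the length trend left HLA-DRA at -2.92 (SE 0.3543, adjusted p = 0.0237), which argues against length. Fewer B cells could not be excluded: the B cell list had a median of -0.9217 (SE 1.229, 9 genes), and its summed CPM was lower in CXCR5hi in both AIT pairs (28.14 against 50.72, and 21.48 against 26.64) and 1.20-fold higher in CXCR5hi in allergic donors, within 21.48 to 94.04 over all libraries. A biological difference between therapy groups stays open and was not separately tested.

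A sample lay far from the others of its group in 30 of 217 groups of values, where 1 in 20 gives 10.85 for independent values of normal spread. Most values were CPM without a log, and several genes of 1 library can move together. The excess therefore does not show outlying samples. The number given is the gap to the nearest library as a share of the group's range, and no explanation was tested. In CXCR5hi allergic libraries, replicate 2 was highest for CST3 (0.8171) and IL12RB2 (0.8489), and replicate 4 for DUSP4 (0.8389) and RASGEF1B (0.7882). In CXCR5lo allergic libraries, replicate 5 was highest for summed monocyte and myeloid CPM (0.8776), which was 738.3 against 212.1 in the next library, and for CPVL (0.8148), CST3 (0.7241), CYBB (0.7796), LYZ (0.8153), S100A8 (0.753) and S100A9 (0.7456). There, replicate 1 was highest for CCR6 (0.7845) and lowest for CCR7 (0.7945). Replicate 4 was highest for CXCR5 (0.8668) and DUSP4 (0.8231) and lowest for PASK (0.7124), and replicate 2 was highest for IL32 (0.7657) and MLL2 (0.7355). In CXCR5lo AIT libraries, replicate 2 was highest for summed B cell CPM (0.9128), IL32 (0.9567), LAIR2 (0.9558), LGALS3 (0.9044), S100A8 (1) and S100A9 (0.9108). Replicate 4 was highest for CD200 (0.9924) and RGS1 (0.919) and lowest for HMGB2 (0.9642), replicate 3 was highest for CST3 (0.8548) and VCAN (1), and replicate 1 was highest for CPVL (1). The shares of 1 for S100A8, VCAN and CPVL rest on 1 count each over the group.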

How the results depend on the processing

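The alternatives with donor code series, without the donors of highest immediate early counts, with the length trend removed and without marker list genes were chosen after the data had been seen. The others were planned, and all were run. No named gene that passed changed direction. Of all 79 genes called over all donors, 78 kept their sign in the fit with no replicate block. The cause of the changes below was not tested, except that fewer libraries or genes enter where they are left out.

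Of 79 genes between subsets over all donors, DESeq2 called 198, a fit with no replicate block 9, a fit without the 2 allergic donors with highest immediate early counts 26 and the code series with both therapy groups alone 47. Leaving out 1 library gave 35 to 82. The count was 35 to 48 without CXCR5hi allergic replicate 4, CXCR5lo allergic replicate 2, 4 or 5, CXCR5hi AIT replicate 1 or 2 or CXCR5lo AIT replicate 1 or 2, and 51 and 52 without CXCR5hi allergic replicate 5 and CXCR5lo allergic replicate 1. In allergic donors (31 genes), no filter gave 55, DESeq2 95, limma-voom 13, no replicate block 0 in edgeR (255 at unadjusted p under 0.05), the donors of each title tag alone 2 and 104, and the code series of allergic donors only 1. Leaving out 1 library gave 0 to 17. In AIT donors (21 genes), no filter gave 62, DESeq2 233, limma-voom 4 and no replicate block 1. Leaving out 1 library of a pair gave 0 to 6, and leaving out 1 unpaired library 21 to 23.

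For AIT against allergic donors in CXCR5hi (13 genes), RLE size factors gave 3, DESeq2 328, limma-voom 5, omission of immunoglobulin, T cell receptor and HLA genes 2, removal of the length trend 2, the 2 compared groups alone 6, 1 title tag alone 4, code series alone 2 and as a term 3, and omission of the myeloid, platelet and erythroid list genes 2. In these fits the genes higher in AIT, 3 as reported, numbered 62 by DESeq2, 2 by limma-voom and 0 in each of the others. Leaving out 1 library gave 0 to 9. In CXCR5lo (8 genes), DESeq2 gave 63, limma-voom 1, 1 title tag alone 2, code series alone 1 and as a term 5, and omission of the marker list genes 0 in edgeR (1113 at unadjusted p under 0.05). Leaving out 1 library gave 3 to 14. For the difference between therapy groups (1 gene), no filter gave 3, the stricter filter 2, DESeq2 20, limma-voom 0, omission of HLA genes 0, no replicate block 0 in edgeR (184 at unadjusted p under 0.05), and leaving out 1 library 0 to 2. With an estimated correlation, 1 gene list passed for AIT against allergic donors in each subset, in place of 4 and 3.

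Of 3080 values of named genes under an alternative, 2428 lay on the same side of the threshold, 640 no longer passed and 12 newly passed. The sign differed in 98, of which 0 passed in either fit (edgeR, DESeq2 or limma-voom). Over all donors, 16 of 28 named called genes, CXCR5, GZMA and FOXP3 among them, passed in every fit with 1 library left out. For AIT against allergic donors these were 0 of 12 in CXCR5hi and 3 of 8 in CXCR5lo (LYZ, S100A8 and SERPINA1). Simulated 2-fold changes were recovered in 2% and 4% of genes in the comparisons of AIT with allergic donors, so changes of that size were mostly not detectable there.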

Other observations

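Genes in this part were chosen after their values were seen, as were the splits that respect donor code series. The other splits of samples were planned. No list of the genes named here was tested, so they stand for no wider group. Lower in CXCR5hi than in CXCR5lo over all donors were the MHC class II genes HLA-DPA1 (-1.14 ± 0.16), HLA-DPB1 (-1.25 ± 0.24) and HLA-DRB1 (-1.61 ± 0.33). The mitotic checkpoint gene BUB1B (-4.59 ± 0.88), CENPE (-1.94 ± 0.38), WEE1 (-1.74 ± 0.34) and the condensin gene SMC4 (-0.91 ± 0.18) were lower as well, and so were RUNX3, a factor of cytotoxic and Th1 programmes (-0.83 ± 0.17), ID2 (-1.06 ± 0.15), the inhibitory receptor gene LAG3 (-3.11 ± 0.48) and HPGD (-2.94 ± 0.43), which encodes a prostaglandin-degrading enzyme.

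Summed CPM of immediate early genes was 42310 to 52030 in 4 allergic libraries that share a title tag, 6385 to 15450 in the other allergic libraries and 14770 to 24640 in AIT libraries. CXCR5lo AIT replicate 1, which has that tag too, had 24440. The first principal component (27.5% of variance) separated the 2 donor code series.

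Over all donors, 1 of 64 assignments of subset within donors (the real one) gave as many genes as 79, and the highest of the others gave 1. That share lies under 0.05 and is the smallest that 64 assignments allow, so it argues against chance without excluding it. For AIT against allergic donors in CXCR5lo, 1 of 100 drawn splits gave as many as 8 and the highest other 0. Splits that mix the donor code series are not comparable with the real one, so chance was not excluded. Of the possible splits, 15 keep the donors of the code series without AIT on the allergic side, too few for a share under 0.05. In CXCR5hi, 2 of 56 splits gave as many as 13, which has the same limit and does not exclude chance. The other one gave 2073 genes. It follows donor code series and points to a structure of the samples. Of the splits, 10 keep the series without AIT on the allergic side, too few for a share under 0.05 (13 genes against at most 0 in the others). Within the series that holds both therapy groups, 2 genes passed. For the difference between therapy groups, 2 of 21 splits gave as many as 1 gene, with 1 as the highest other, so chance was not excluded. Splits were too few for a share under 0.05 in allergic donors (16 splits, 31 genes against at most 0 in the others) and AIT donors (2 splits, 21 genes against at most 0).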
